A study of Danio rerio with 3 samples.

How the data were processed

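The samples were 3 two-colour arrays, each with a pool of 50 FoxH1 morphants and a pool of 50 control morphants, collected at 40% epiboly. Groups and dyes were taken from the labels. Per the design text, the work was repeated 3 times independently with 1 dye swap. The accounts of the labelling differ: the design text speaks of amplified RNA, and the labels' protocol of total RNA reverse transcribed with aminoallyl dUTP. The scanner and its software are not given in the sources used here.

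Per the file headers, each array's table holds a mean spot intensity for a red and a green column, the local background intensity and its SD, a ratio, an array constant and a quality score. The intensity columns were already background-subtracted by the authors. The authors made the ratio by dividing red over green by 1 constant per array (2.8186, 2.7008 and 0.3985), a relation that held within 1% for 99.37% or more of the spots on each array. The deposited quality score is 0 for 15.4%, 15.4% and 13.1% of oligo spots on arrays 1, 2 and 3, and such spots were left out as poor. The authors' deposited log2 matrix equals minus log2 of that ratio within 0.01 at all 35328 values of each array, with medians of -0.02, 0.00 and 0.00. Its scale and centring are thereby known, and it has no correction for intensity. Its direction is the one discussed for array 3 in the results.

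Ratios were computed as log2 of green over red from the deposited intensities, which needed no further background correction. Each array was normalized by loess (span 0.3). Replicate spots of an oligo were averaged. Control spots, empty spots and oligos without an accession were left out. An oligo was tested if usable on all 3 arrays and above 2 background SDs in either column on at least 2 arrays; this filter removed no oligo that was usable on all 3 arrays. No tested gene had all its oligos below background in 1 column on every array. Subtracting the local background and leaving out spots at or below 0 is identical to the main setting here.

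Gene symbols came from the arrays' RefSeq accessions through a table for assembly GRCz12tu (1302 of 1375 such oligos found), from the symbol and title columns, and from shared accessions or UniGene clusters. Of 33741 oligos, 3148 (9.3%) had 1 symbol, covering 1095 genes, and 30593 had none and were not named. A gene's value is the mean of its oligos. UniGene clusters with several symbols (3) were not used.

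Tests used limma 3.58.1 in R 4.3.3: lmFit and eBayes on the 3 log2 ratios, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no dye term. Without a dye term, part of each oligo's dye effect stays in the mean, because 1 of 3 arrays was swapped. Lists were tested with camera (preset correlation 0.01), with an estimated correlation and fry beside it. With an estimated correlation, camera's test has only the residual degrees of freedom of the 3 arrays. A list can then hardly pass, so a missed threshold there says little for or against it. An exact sign-flip test on 3 arrays, taken on both sides, cannot go below p = 0.25. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

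The tests, lists and naming rule were fixed before the data were examined. The planned signs were for Cy5 over Cy3, from the dyes in the labels, and with red taken as Cy5 on every array they give the alternative with array 3 turned. The reading of array 3 by sample, used for all main values, was adopted after the data were seen. Named genes are foxh1; up to 12 per direction by size among genes past the threshold with 1 sign on all 3 arrays, filled by the smallest p where fewer pass; and, from each list, up to 4 members past the threshold or else up to 3 with the smallest p, with up to 8 for Nodal components, mesendoderm and keratins. The 18 lists were Nodal components, mesendoderm Nodal targets, dorsal organizer, ventral and BMP, keratins, other enveloping layer genes, yolk syncytial layer, Fgf and Wnt targets, adhesion and movement, pluripotency regulators, cleared maternal transcripts, germ cells, neural ectoderm, later stages, p53 and stress, cell cycle, housekeeping, and ribosomal proteins.

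The fits were tested on simulated data, with 100 features changed by 1 log2 unit and 100 by 2 among 26222 oligos or 1058 genes and with the arrays' own spread. Without dye effects, 37 and 60 of 100 oligos and 78 and 96 of 100 genes were recovered at the smaller and larger change. With dye effects of the size seen on the arrays, 0 and 0 of 100 oligos and 0 and 28 of 100 genes were recovered. A dye term then gave 0 and 0 of 100 oligos and 76 and 84 of 100 genes. Camera called a mesendoderm list lowered by 0.5 in 100 of 100 draws, with 1.22 other lists per draw, some of which share members with it. With no shift it called the list in 0 draws and 0.04 other lists per draw. Genes were simulated as independent, which real genes are not.

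Alternatives covered the background, normalization, filters, quality, dye term, weights, test, threshold, deposited values, each array left out, the brightest oligo, and list tests. Added after the data were seen were a floor from random negative controls, the dye term at adjusted p under 0.1 and lists without shared genes. So were 2 restrictions on oligos, and groups by title words, also with array 3 turned. Array 3 turned follows the planned signs with red taken as Cy5, and it was made an alternative after the data were seen. Normexp with offset 50, planned for intensities not yet background-corrected, was made an alternative in the same way.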

Results

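The data were 3 two-colour hybridisations of zebrafish RNA to printed arrays of long oligonucleotides (oligos) from 3 sets. FoxH1 is a forkhead transcription factor that acts with Smad proteins downstream of Nodal signals in early embryos. On each array, RNA from a pool of 50 embryos injected with a morpholino (an antisense oligo that blocks translation or splicing) against FoxH1 was hybridised together with RNA from a pool of 50 embryos injected with a control morpholino. All pools were collected at 40% epiboly, when cells have begun to spread over the yolk. The design text describes 3 independent repeats, so each array is taken as 1 pair of pools (n = 3). That independence rests on this text alone, since the titles of the 3 arrays share a number whose meaning is not given. Morphant RNA carried Cy3 on arrays 1 and 2 and Cy5 on array 3, the dye swap. Median intensities of the oligo spots were 467.2, 338 and 161.6 in the control column and 190.8, 146.6 and 383.7 in the morphant column of arrays 1, 2 and 3. Of 33741 distinct oligos, 26222 were usable on all 3 arrays, and 1058 genes with a symbol were tested. The number of arrays limits the precision of every value.

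The direction of the ratio on array 3 rests partly on the data. The labels fix which dye each pool carried, and on arrays 1 and 2 the green column of the spot tables holds the morphant. On array 3 the same holds only if the columns are ordered by sample, and 3 measurements bore on this. The red column had the higher local background at 5.5% and 5.2% of spots on arrays 1 and 2 and at 94.1% on array 3. Random negative control spots had green-over-red ratios that correlated at r = 0.90 between arrays 1 and 2. Between the mean of these arrays and array 3, the correlation was r = -0.70 (rho = -0.45, permutation p = 1e-05 over 132 spots, two-sided). This p is the smallest the permutations can give. For Arabidopsis control spots, the values against array 3 were r = -0.87 and rho = -0.84 (permutation p = 1e-05 over 35 spots). Of 188 random and 173 Arabidopsis spots, only those above 2 background SDs in both columns on all 3 arrays entered. Spots with a quality score of 0 were also left out. Both correlations are across spots, which are not independent replicates, and they were computed after the columns had been seen. Repeated spots of an oligo were not averaged here, so the permutations treat them as separate units. The columns of array 3 were read in this way only after these values had been seen. Ratios are given as green over red, morphant over control, on all 3 arrays. Values with array 3 turned (its sign reversed) are given beside the counts of oligos and genes and beside each list that passed.

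**Figure D1:**
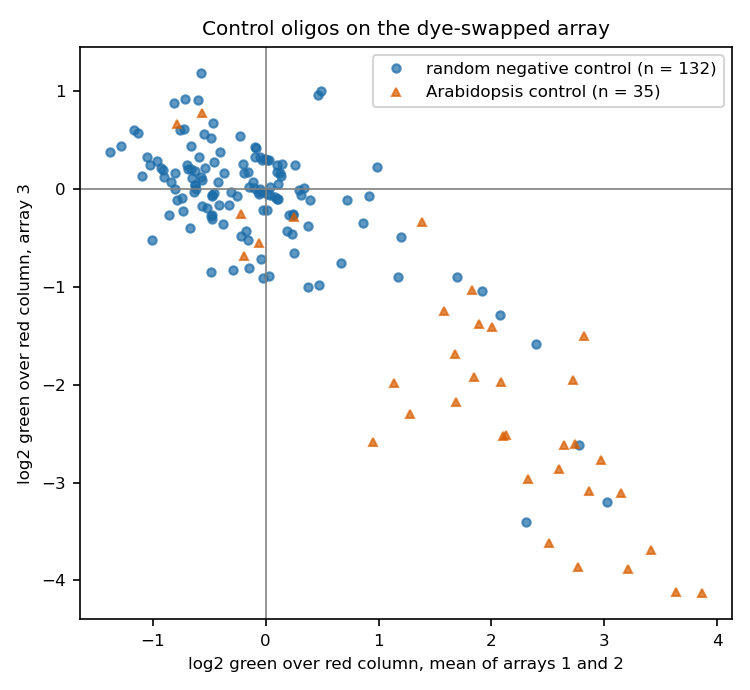
Log2 green over red after loess for 132 random negative control spots (circles) and 35 Arabidopsis control spots (triangles). Only spots above background in both columns on all 3 arrays are shown. The x axis is the mean of arrays 1 and 2, and the y axis is array 3. Points run from the upper left to the lower right, with r = -0.70 for the random and r = -0.87 for the Arabidopsis spots.

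Whether FoxH1 knockdown altered transcript levels was asked first for single genes. No gene passed the test, and values of the genes named by the fixed rule are given as measurements. The T-box gene tbx6 was at a log2 morphant-over-control ratio of -2.78 ± 0.41 (SD, n = 3 arrays; 1 oligo), the brachyury homologue tbxta at -2.19 ± 0.59, and tbx16 at -1.19 ± 0.07. The oscillating hairy-related gene her7 was at -2.45 ± 0.89. The endoderm regulators gata5 and foxa3 were at -1.11 ± 0.27 and -0.97 ± 0.15. Above 0, the germ cell gene dazl was at 1.96 ± 0.75, the cyclin gene ccnb1 at 0.94 ± 0.10 (1 oligo), and her5, otx1 and irx7 at 1.24 ± 0.16, 0.87 ± 0.23 and 0.85 ± 0.08. Mean log2 intensities of tbx6 (8.04) and gata5 (7.88) lay between the medians of Arabidopsis (5.17) and random negative (8.47) controls.

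None of these genes passed limma's test after Benjamini-Hochberg adjustment. The count was 0 of 26222 oligos (lowest adjusted p = 0.282) and 0 of 1058 genes (lowest adjusted p = 0.425) at an adjusted p under 0.05, and the one-sample test without moderation also gave 0 at both levels. On simulated data with dye effects, limma recovered 0 of 100 oligos and 28 of 100 genes changed by 2 log2 units. The main fit's counts of 0 therefore do not show that transcripts were unaltered. With a dye term, 0 of 100 oligos and 84 of 100 genes were recovered there. On the arrays that fit gave 0 genes at an adjusted p under 0.05 (lowest 0.0660) and 138 under 0.1. At an unadjusted p under 0.05 there were 2975 oligos, with 1311.1 expected by chance, and 82 genes, with 52.9 expected. The named genes are those with the smallest p and 1 sign on all 3 arrays, so their values are given as measurements that did not pass. With array 3 turned, 2498 oligos and 309 genes passed, and without replicate 3, 5443 oligos and 489 genes passed. With the columns read by sample, the oligos' own dye effects enter both of these settings with 1 sign on every array.

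The other genes named by the same rule, all with 1 sign on 3 arrays, covered several functions. Lower values were measured for the sodium pump subunit gene atp1b1a (-1.69 ± 0.45), the laminin chain gene lamb1a (-2.12 ± 0.55, 1 oligo), krt4 (-1.26 ± 0.09), siah2l (-1.22 ± 0.20, 1 oligo), elf2b (-1.05 ± 0.26) and the Notch ligand gene dlc (-1.05 ± 0.29). One of the 3 dlc oligos had the opposite sign, and with oligos above background in both columns dlc was at 0.022. Higher values were measured for phc2a (1.84 ± 0.50, 1 oligo), gstp1.2 (1.16 ± 0.12), the clock gene bmal1a (1.22 ± 0.45), sinup (1.03 ± 0.22, 1 oligo), the Wnt effector gene lef1 (1.01 ± 0.20), hic1l (0.87 ± 0.10) and the Wnt receptor gene fzd4 (0.75 ± 0.11).

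**Figure D2:**
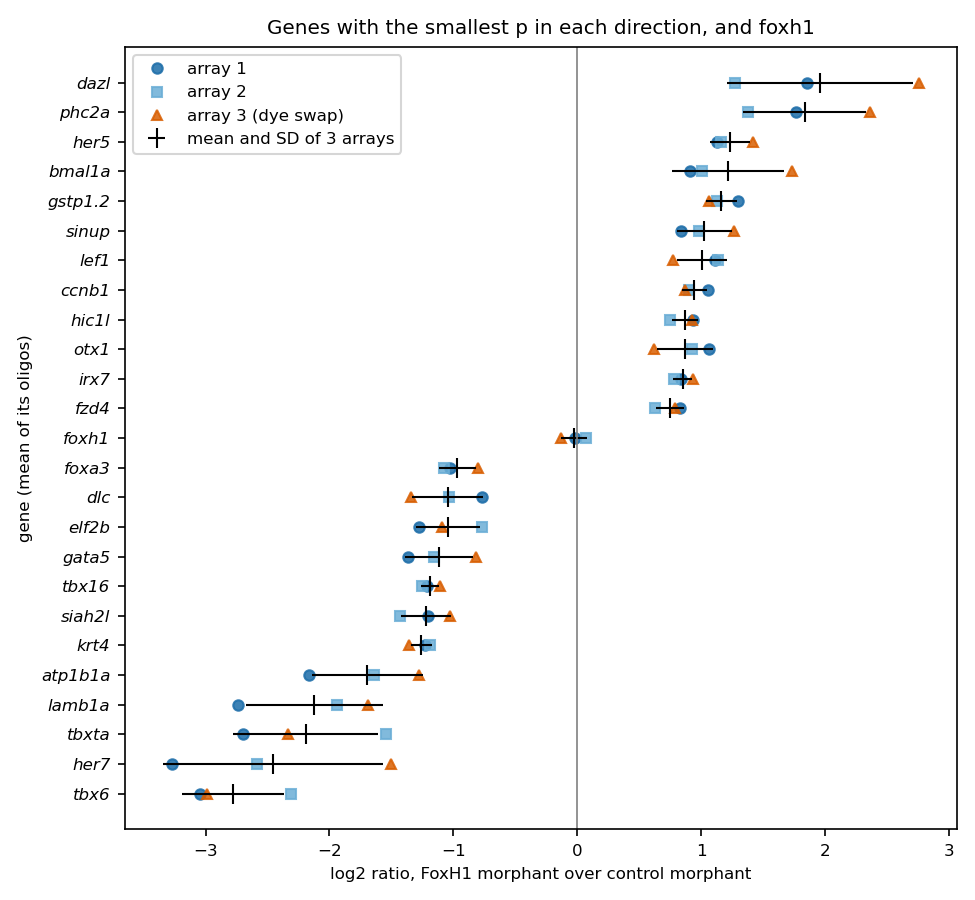
Log2 ratio of FoxH1 morphant over control morphant for 25 genes, as the mean of each gene's oligos on array 1 (circles), array 2 (squares) and array 3 (triangles), with the mean and SD of the 3 arrays in black. Values run from -2.78 for tbx6 to 1.96 for dazl, and foxh1 lies at -0.03.

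Genes known as Nodal targets in mesoderm and endoderm were lower as a group in the morphants. The shift passed limma's camera test (adjusted p = 2.1e-06 over 18 lists), but not with an estimated correlation between genes (adjusted p = 0.379). That estimate, 0.015, was near the preset 0.01, so a stronger correlation between genes did not end the call. The list also missed the threshold with fry (adjusted p = 0.122). The list's 24 measured members had a mean log2 ratio of -0.48 ± 0.19 (SD over 3 arrays) and a median of -0.43, and 13 were lower and 0 higher on all 3 arrays, against 16.3% lower and 10.9% higher among all 1058 genes. Besides tbxta, tbx16, gata5 and foxa3, the endoderm regulator sox32 was at -1.22 ± 0.49, lhx1a at -0.66 ± 0.08, gata6 at -0.76 ± 0.41 and fgf3 at -0.62 ± 0.16. No member passed over all genes, and 4 (tbx16, tbxta, foxa3 and gata5) passed when adjusted over the list alone. Without replicate 3 the list still passed (mean -0.42, adjusted p = 0.000591), and with array 3 turned the mean was -0.040, with 3 lower and 5 higher on all 3 arrays (adjusted p = 0.736).

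Marginal targets of Fgf and Wnt signals formed a mixed group with a lower mean. Camera gave an adjusted p = 0.0188, against an adjusted p = 0.379 with an estimated correlation and 0.295 with fry. With a dye term the group's mean was -0.55 and camera's adjusted p = 0.0626. Its 23 measured genes had a mean of -0.50 ± 0.16 (SD over 3 arrays), with 7 lower and 3 higher on all 3 arrays. The caudal-related gene cdx4 was at -1.65 ± 0.93 (1 oligo), whereas her5 and lef1 lay above 0. Adjusted over the list alone, 7 genes passed, of which her5 and lef1 were higher and the others lower. Without replicate 3 the list did not pass (mean -0.38, adjusted p = 0.229), nor did it with array 3 turned (mean -0.054, 3 lower and 7 higher, adjusted p = 0.736). It shared 4 measured genes with the mesendoderm list, and without them it did not pass (mean -0.40, adjusted p = 0.337).

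Dorsal, ventral and yolk syncytial genes were lower by camera with the preset correlation, but several alternatives ended these calls. The 16 dorsal organizer genes had a mean of -0.21 ± 0.29 (adjusted p = 0.0342, and 0.379 with an estimated correlation), and dkk1b and otx2b were at -0.53 ± 0.34 and -0.48 ± 0.36. The sign of dkk1b turned with the brightest oligo (0.18) and with array 3 turned (0.082). The 18 ventral and BMP genes had a mean of -0.28 ± 0.38 (adjusted p = 0.0231, and 0.546 with an estimated correlation), from -0.068, -0.056 and -0.73 on arrays 1, 2 and 3, with the ligand genes bmp4 at -0.99 ± 0.29 and bmp7a at -1.08 ± 0.36. The 11 yolk syncytial layer genes had a mean of -0.32 ± 0.14 (adjusted p = 0.0402, and 0.379 with an estimated correlation). Of these, gata5, sox32 and gata6 are also in the mesendoderm list, and fn1a was at 0.57 ± 0.05. No gene of these 3 lists passed over all genes or adjusted over the list alone. Without the genes shared with the mesendoderm list, the dorsal and yolk syncytial lists were past the threshold no longer (adjusted p = 0.337 and 0.728). Without replicate 3 none of the 3 lists passed, with means of 0.015, -0.019 and -0.23 (adjusted p = 0.494, 0.504 and 0.229) for dorsal, ventral and yolk syncytial genes. Their means with array 3 turned were 0.16, 0.20 and 0.0059 (adjusted p = 0.842, 0.922 and 0.736). The dorsal list also missed the threshold with no background correction (adjusted p = 0.121), median centring (0.0635), loess within print-tip blocks (0.0668), oligos above background in both columns (0.118), poor spots kept (0.0701), oligos usable on at least 2 arrays (0.0637), deposited values (0.0616), the brightest oligo per gene (0.780), normexp (0.0515) and without oligos named by UniGene cluster (0.0574). The yolk syncytial list missed it with a dye term (adjusted p = 0.104), median centring (0.0637), deposited values (0.0664), the brightest oligo per gene (0.252) and without the Compugen oligos (0.117). Its means there ran from -0.25 with the brightest oligo to -0.47 without the Compugen oligos, with -0.36 for the dye term.

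Keratins of the outer epithelial layer were lower in the morphants. Camera gave an adjusted p = 0.00158, against an adjusted p = 0.379 with an estimated correlation and 0.0765 with fry. Of 23 keratins in the fixed list, 3 were measured. All 3 lay below 0 on all 3 arrays, with krt4 at -1.26 ± 0.09, cyt1 at -0.80 ± 0.47 and krt5 at -0.49 ± 0.17. Without replicate 3 the mean was -0.87, and the list did not pass (adjusted p = 0.0710). The mean with array 3 turned was -0.31, and 0 genes were lower on all 3 arrays (adjusted p = 0.736). One gene, krt4, passed when adjusted over the list alone. The list was fixed because the study is remembered to have examined keratins on these samples, so neither count is independent evidence. Of the 6 krt5 oligos, 4 were below 0 and 2 above. Some krt5 oligos and the cyt1 oligo at -0.13 were named only through a shared UniGene cluster. Without oligos named in this way the list's mean was -1.20, against -0.85 with them. The 11 other genes of this layer had a mean of -0.02 and a median of 0.09 (adjusted p = 0.870), with the claudin gene cldnf at -0.84 ± 0.22, klf2b at 0.76 ± 0.18 and the plakoglobin gene jupa at -0.51 ± 0.23.

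Maternal transcripts that embryos clear around the onset of zygotic transcription were higher as a group. Camera gave an adjusted p = 0.00158, against an adjusted p = 0.379 with an estimated correlation and 0.165 with fry. The 11 measured members had a mean of 0.48 ± 0.22 (SD over 3 arrays), and 5 were higher and 1 lower on all 3 arrays. Beside ccnb1, the zinc finger gene cth1 was at 1.18 ± 0.60 and ybx1 at -0.76 ± 0.41. Without replicate 3 the mean was 0.61, and the list did not pass (adjusted p = 0.229). The mean became 0.33 with array 3 turned, with 4 higher and 0 lower on all 3 arrays (adjusted p = 0.922). No member passed over all genes or adjusted over the list alone.

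**Figure D3:**
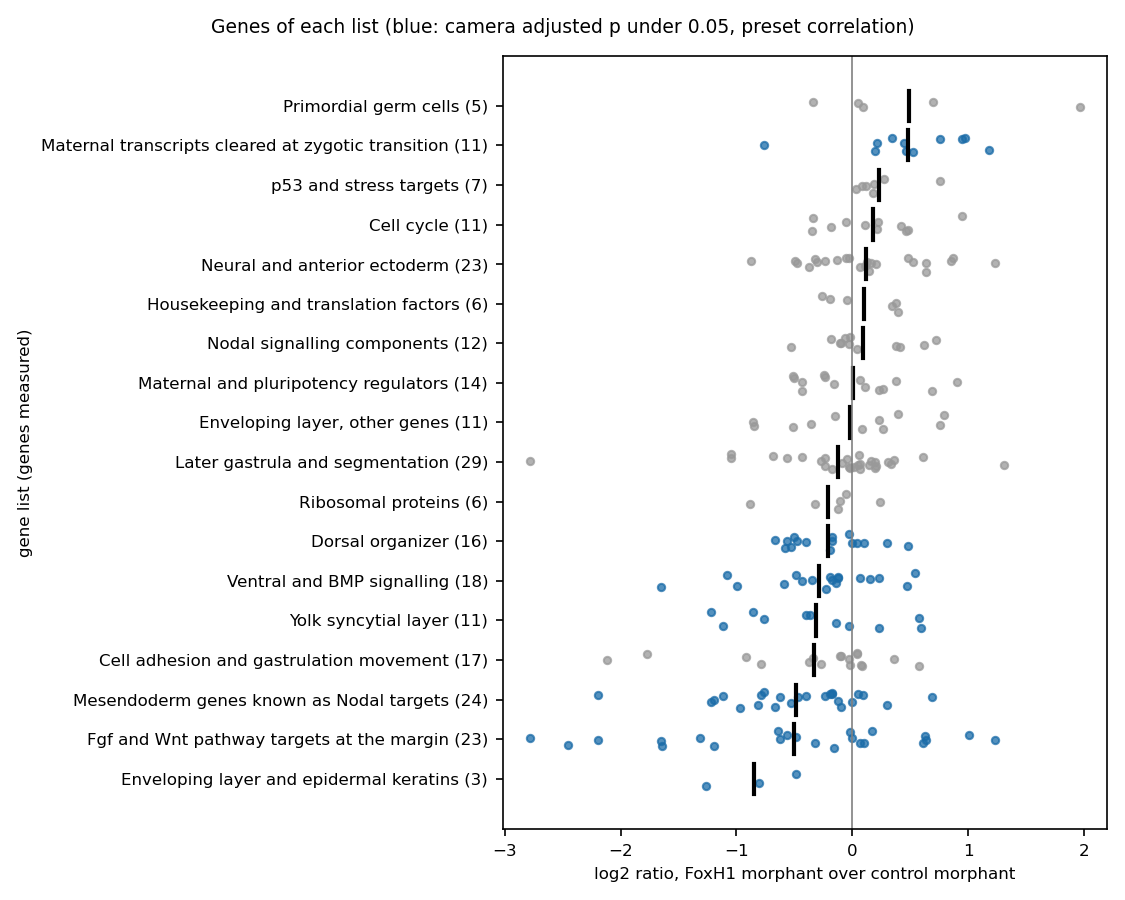
Log2 ratio of morphant over control (x axis, mean of 3 arrays) for the measured genes of the 18 lists (points; number of genes in brackets), with the list mean as a black bar. The 7 lists in blue passed camera with the preset correlation, and 0 did so with an estimated one.

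The remaining 11 lists did not pass camera. Nodal pathway components, 12 genes, had a mean of 0.10 and a median of -0.02 (adjusted p = 0.811), with gdf3 at 0.62 ± 0.11, skia at -0.53 ± 0.13, smad2 at 0.73 ± 0.87, lft2 at 0.41 ± 0.83, smad4a at 0.38 ± 1.37, lft1 at -0.19 ± 0.70, ndr2 at -0.10 ± 0.41 (1 oligo) and acvr2ba at -0.06 ± 0.19 (0.029 with loess within print-tip blocks). Neural and anterior ectoderm genes had a mean of 0.12 over 23 genes (adjusted p = 0.561), with 3 lower and 4 higher on all 3 arrays. The 5 germ cell genes had a mean of 0.49 (adjusted p = 0.318), where nanos3 was at 0.70 ± 0.82 and elavl1b at -0.34 ± 0.04; dazl passed when adjusted over the list alone. Pluripotency regulators had a mean of 0.01, a median of -0.05 and a test direction below 0 (14 genes, adjusted p = 0.870), or a mean of -0.071 with median centring (adjusted p = 0.473), with sox19b at 0.90 ± 0.33, sox11a at -0.51 ± 0.06 and vent at -0.44 ± 0.09. Adhesion and movement genes had a mean of -0.33 over 17 genes (adjusted p = 0.235), with snai1b at -0.91 ± 0.59, or 0.0015 with oligos above background in both columns and 0.24 with the brightest oligo. Genes of later stages had a mean of -0.12 and a median of 0.02 over 29 genes (adjusted p = 0.450), with cryaa at -1.05 ± 1.24 (1 oligo) and tbx6 passing when adjusted over the list alone.

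Markers of stress and of general cell functions gave list means that did not pass. The 7 p53 and stress targets had a mean of 0.23 (adjusted p = 0.293), with casp8 at 0.76 ± 0.49, baxa at 0.18 ± 0.51 and mdm2 at 0.28 ± 1.11. Their mean was 0.58, 0.36 and -0.25 on arrays 1, 2 and 3. It was 0.058 without replicate 1 and 0.47 without replicate 3. The 11 cell cycle genes had a mean of 0.18 (adjusted p = 0.318), with rrm1 at 0.46 ± 0.30 and ccnd1 at -0.34 ± 0.07. The 6 ribosomal protein genes had a mean of -0.21 (adjusted p = 0.293), with rpl35 at -0.89 ± 0.48 (1 oligo) and rps18 at 0.24 ± 0.31. The 6 housekeeping genes had a mean of 0.10 (adjusted p = 0.811), or -0.16 with median centring (adjusted p = 0.749), with eef1g at 0.38 ± 0.24 (1 oligo), b2m at -0.26 ± 0.25 and actb1 at 0.39 ± 1.19. Several named genes of the lists that did not pass had the other sign under at least 1 alternative. These were acvr2ba, b2m, baxa, dlc, eef1g, elavl1b, foxh1, lft1, mdm2, ndr2, rps18, skia, smad4a, snai1b and vent.

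The targeted transcript, foxh1, was at -0.03 ± 0.10 (SD, n = 3 arrays, adjusted p = 0.970), with -0.02, 0.07 and -0.13 on arrays 1, 2 and 3. Its 2 oligos were at -0.00 ± 0.39 and -0.05 ± 0.21. A morpholino need not alter the level of its target mRNA, so this value checks little.

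Over all tested oligos, morphant-over-control ratios correlated at r = 0.82 (rho = 0.82) between arrays 1 and 2, at r = -0.35 (rho = -0.20) between arrays 1 and 3, and at r = -0.47 (rho = -0.34) between arrays 2 and 3. The latter become, with array 3 turned, 0.35 and 0.47. These correlations are across oligos. Different oligos of a gene were compared as separate measurements on the same arrays: in 365 of 836 genes with at least 2 oligos (43.7%, 95% Wilson interval 40.33 to 47.04) all oligos had the same sign, against 31.4% after shuffling oligos among genes. The correlation between oligos of a gene was 0.22 over 2401 pairs, and at most 0.03 in 1000 shuffles. The share was 32.9% and the correlation -0.05 with array 3 turned, against 29.7% and at most 0.007 in shuffles of that setting. For tbx16 the 3 oligos were at -1.23 ± 0.23, -1.11 ± 0.21 and -1.23 ± 0.20, and for krt4 at -0.73 ± 0.14, -1.51 ± 0.03 and -1.53 ± 0.41. Oligos of other genes spread more widely. Those of tbxta ran from -3.76 ± 1.45 to -1.15 ± 0.90, and those of cyt1 were at -1.47 ± 0.55 and -0.13 ± 0.40. The range was -2.25 ± 0.67 to 1.30 ± 3.92 for krt5, and -0.96 ± 0.50 to 0.82 ± 3.09 for lft1. The highest lft1 oligo was at 2.52, 2.69 and -2.75 on arrays 1, 2 and 3.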

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

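The fit with a dye term, the test of the p53 list and the correlations between arrays over all oligos were planned. So was camera with an estimated correlation for the fixed lists. The other tests in this part were chosen after the results were seen. A signal appeared in spots outside the comparison of morphants with controls: random negative control oligos, designed without a zebrafish target, had a median log2 intensity of 8.47, with medians of 704.3, 522.4 and 197.1 in the control column of arrays 1, 2 and 3 against 28.9, 3.7 and 7.6 for empty spots.

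The first pattern is that array 3 ran against arrays 1 and 2 over all oligos (r = -0.35 and -0.47), though hardly among the 6556 oligos of highest intensity (r = -0.06 and -0.13, rho = 0.03 and -0.01). Columns that hold the same dye on every array would keep the higher background in 1 column, but 94.1% of spots on array 3 had it in the red column, against 5.5% and 5.2%. A different response of the third pair of pools would leave oligos without a zebrafish target out, but the Arabidopsis oligos correlated at r = -0.87. Columns ordered by sample, with dye effects that turn over on the swapped array, require a negative correlation of the random control oligos, and it was r = -0.70. This explanation may therefore hold, as a hypothesis found and tested on the same arrays.

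The second pattern is the lower mesendoderm list. Dye effects alone would turn over on array 3, but the list's mean was -0.49, -0.29 and -0.67 on arrays 1, 2 and 3. With a dye term the mean was -0.53 and camera's adjusted p = 0.000979, although with an estimated correlation it was 0.656. That fit leaves the swapped array 3 no residual, so its own spread is unmeasured, and camera's preset p is taken across genes. Dye effects as the whole cause are thus argued against only as far as 1 swapped array can. A general lowering of zygotic transcripts cannot be told apart: the neural list lay 0.60 above the mesendoderm list (permutation p = 0.00048 over 23 and 24 genes), but its median log2 intensity of 8.56 was near that of random negative controls, 8.47, and above that of Arabidopsis controls, 5.17, so the floor is not settled. That permutation shuffles genes and carries no spread between arrays. The neural mean was 0.42, 0.29 and -0.36 on arrays 1, 2 and 3, and 0.0010 with a dye term. Injury with p53 activation also stays open, since the p53 list had an adjusted p = 0.293 over 7 genes, which excludes nothing. The loss of FoxH1 activity itself is a biological explanation that the design names, and it stays open and untested because the arrays hold 1 FoxH1 morpholino and no rescue.

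The third pattern is the higher maternal list. Its mean was 0.63, 0.58 and 0.23 on arrays 1, 2 and 3, where dye effects alone would turn over on array 3. With a dye term camera's adjusted p = 0.000500, although with an estimated correlation it was 0.656. The same limits of the dye-term fit hold here. Dye effects as the whole cause are thus argued against only as far as 1 swapped array can. Slower development of morphants may contribute, and oligos from ovary libraries had a mean of 0.16 that array 3 carried (0.075, -0.050 and 0.46 on arrays 1, 2 and 3), and with an estimated correlation their p missed the threshold (adjusted p = 0.694), so this cannot be told apart from a direct effect at 1 stage.

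Turning the sign of 1 array at a time gives 4 patterns of the 3 arrays, too few for a share under 0.05. The pattern with the columns of array 3 read by sample, adopted after the data were seen, gave 0 oligos, 0 genes and 7 lists. The highest of the others gave 2498 oligos and 309 genes; it is the one with array 3 turned, which takes red as Cy5 on every array and points to a structure of the arrays that follows the dyes. For lists, the highest of the others gave 0.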

How the results depend on the processing

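The floor from random negative controls and the dye term at an adjusted p under 0.1 were chosen after the data were seen. So were the alternatives without shared genes, without oligos named by UniGene cluster and without the Compugen oligos. Array 3 turned is what the planned signs give with red taken as Cy5, and it was made an alternative after the data were seen. Normexp, planned for intensities not yet background-corrected, was made an alternative in the same way. The mesendoderm list had a mean below 0 under every alternative that left it testable (the floor from random negative controls did not), with adjusted p from 1.4e-07 to 0.736. The counts at an adjusted p under 0.05 were 0 for oligos and genes except with array 3 turned (2498 oligos and 309 genes) and in the ranges without 1 replicate (0 to 5443 oligos and 0 to 489 genes, the highest without replicate 3). At an unadjusted p under 0.05 there were 2975 oligos and 82 genes, and with a dye term at an adjusted p under 0.1 there were 138 genes. The number of lists past the threshold was 0 with an estimated correlation, 0 with fry, 0 with array 3 turned, 4 without shared genes, and 1 to 7 without 1 replicate, the lowest without replicate 3. Above the 95th percentile of random negative controls, where 632 oligos are left, none of the 7 lists could be tested, so the count of 0 there says nothing about them. Without replicate 3 both remaining arrays have the same dyes, so dye effects are not separable; without replicate 1 or 2 the test rests on 2 arrays. The share of genes whose oligos had 1 sign ranged from 36.7% to 47.4% without 1 replicate. The main fit is already paired, because each ratio compares the pair of pools on its array. No further pairing was possible, since a number that the titles share is the same for all 3 arrays. Signal over background limits dim oligos: random negative controls had a median log2 intensity of 8.47, and 50.7% of tested oligos lay above it. Several named genes lay below it, among them cdx4 (6.89), fgf3 (8.03) and tbx6 (8.04).

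For 67 named genes, 1321 of 1410 values under 22 settings had the direction and side of the threshold of the main value, 56 passed where the main value did not, and 33 had the other sign. At an adjusted p under 0.05, genes passed only with array 3 turned or without replicate 3, and none in the main fit. The side of the threshold was thus fixed elsewhere, and the setting without a filter on dim oligos equals the main one. This tally therefore measures little beyond direction. For the 18 lists, 308 of 381 values were unaltered in this sense, 42 kept the sign but no longer passed, and 31 had the other sign. Among the latter, the dorsal list without replicate 3 and the dorsal, ventral and yolk syncytial lists with array 3 turned also no longer passed. The cause of the other signs was not tested. Without background correction, lft1 was at 0.0027 and the other enveloping layer list at 0.026. With median centring, the housekeeping list was at -0.16 and the pluripotency list at -0.071. With loess within print-tip blocks, acvr2ba was at 0.029. With oligos above background in both columns on all 3 arrays, b2m was at 0.015, dlc at 0.022, snai1b at 0.0015 and the other enveloping layer list at 0.023. With a dye term, mdm2 was at -0.042, ndr2 at 0.0094, smad4a at -0.017, the housekeeping list at -0.034, the pluripotency list at -0.020 and the Nodal component list at -0.0099. With the swapped array weighted as both others, mdm2 was at -0.042, ndr2 at 0.0094 and smad4a at -0.017. With the deposited log2 values, the housekeeping list was at -0.16 and the pluripotency list at -0.077. With the brightest oligo per gene, b2m was at 0.30, dkk1b at 0.18, elavl1b at 0.018, rps18 at -0.16, skia at 0.21, snai1b at 0.24 and vent at 0.28. With array 3 turned, baxa was at -0.32, dkk1b at 0.082, eef1g at -0.060, lft1 at 0.48, foxh1 at 0.063, the dorsal list at 0.16, the other enveloping layer list at 0.068, the later stage list at 0.23, the ventral list at 0.20 and the yolk syncytial list at 0.0059. With normexp and an offset of 50, the other enveloping layer list was at 0.012. Above the 95th percentile of random negative controls, vent was at 0.28, the housekeeping list at -0.18 and the later stage list at 0.040. Without oligos named by UniGene cluster, the housekeeping list was at -0.11. Without the Compugen oligos, rps18 was at -0.054, smad4a at -0.0050, the housekeeping list at -0.094, the pluripotency list at -0.014 and the Nodal component list at -0.011. Without genes shared with the mesendoderm list, the pluripotency list was at -0.044. Ranges without 1 replicate were -0.060 to 0.92 for mdm2, -0.31 to 0.099 for ndr2, -0.017 to 1.17 for smad4a, -0.050 to 0.38 for the housekeeping list, -0.027 to 0.36 for the neural list, -0.015 to 0.31 for the Nodal component list, -0.15 to 0.036 for acvr2ba, -0.022 to 0.051 for the pluripotency list, -0.11 to 0.38 for baxa, -0.41 to 0.22 for lft1, -0.31 to 0.015 for the dorsal list, -0.40 to -0.019 for the ventral list, -0.052 to 0.039 for the other enveloping layer list, -0.24 to 0.083 for the later stage list and -0.074 to 0.027 for foxh1.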

Other observations

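The groups and single oligos in this part were chosen after the data were seen. Most oligos had no symbol, so oligos were also grouped by words in their titles; 47 words were tried, camera was adjusted over all 47, and none passed with an estimated correlation (lowest adjusted p = 0.559). The 84 oligos with keratin in the title had a mean log2 ratio of -0.66 ± 0.32 (SD over 3 arrays), and 47 were lower and 1 higher on all 3 arrays (adjusted p = 1.2e-12 with the preset correlation). Their mean with array 3 turned was 0.03, with 7 lower and 23 higher (adjusted p = 0.751). The 429 ribosomal protein oligos had a mean of -0.23 ± 0.06, with 178 lower and 14 higher (adjusted p = 1.6e-08). Over all tested oligos, 17.6% were lower and 17.0% higher on all 3 arrays. Several oligos of 1 gene can fall under a word. The counts and the preset p-values for words treat them as separate members, though they are not independent. At gene level the fixed lists held 3 keratin and 6 ribosomal protein genes (camera adjusted p = 0.00158 and 0.293). Titles with bmp or bone morphogenetic protein had a mean of -0.42 over 26 oligos (adjusted p = 0.00124), gata of -0.49 over 13 (adjusted p = 0.00894), laminin of -0.47 over 11 (adjusted p = 0.0163, and 0.0590 with a dye term), and splicing or ribonucleoprotein of -0.12 over 123 (adjusted p = 0.00774). Cyclin titles had a mean of 0.35 over 60 oligos (adjusted p = 0.000420) and kinesin titles of 0.24 over 30 (adjusted p = 0.0446, and 0.0678 with a dye term). None of these words passed with array 3 turned; immunoglobulin (mean 1.23 over 36 oligos, adjusted p = 2.9e-07), hox or homeobox (0.43 over 198) and notch or delta (0.36 over 93, adjusted p = 0.0492 for both) passed instead.

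Some words name the source of a cDNA library rather than a gene family. The 739 oligos from ovary libraries had a mean of 0.16 ± 0.26 (SD over 3 arrays), from 0.075, -0.050 and 0.46 on arrays 1, 2 and 3, with 199 higher and 64 lower on all 3 arrays (adjusted p = 0.0236). The 1097 from shield stage libraries had a mean of -0.21 ± 0.19, from -0.31, -0.34 and 0.0045 on arrays 1, 2 and 3, with 170 higher and 353 lower (adjusted p = 0.00124). With an estimated correlation the adjusted p were 0.694 and 0.571. The 3334 from adult male, kidney, retina, brain or olfactory libraries had a mean of -0.00032 (adjusted p = 0.847). Turning array 3 gave means of -0.14, -0.22 and -0.10 (adjusted p = 0.0532, 0.0141 and 0.0532) for ovary, shield stage and adult libraries.

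Single oligos near the top of the ranking, picked after their values were seen, included one titled as the oocyte linker histone H1M at 2.17 ± 0.16, one titled aldolase B at -1.52 ± 0.17 and one titled epiplakin, a cytolinker of epithelia, at -2.05 ± 0.36 (SD, n = 3 arrays). None passed limma's test (adjusted p = 0.282 for each).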
